A study of Mus musculus with 6 samples.

How the data were processed

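The series holds CITE-seq data, in which messenger RNA and surface proteins tagged with antibody barcodes are counted in the same single cells, from the thymus of young wild-type male mice. Per the labels' protocols, haematopoietic cells other than mature T cells were sorted by flow cytometry. Mice were left untreated or received dexamethasone, a synthetic glucocorticoid that kills immature thymocytes, 18 h or 4 days before the thymus was taken, at 200 µg per 10 g. Each condition has 2 hashed samples, which are samples whose cells carry a hashtag antibody, and the 6 hashed samples were run as 3 pools. Pool A held untreated 1 and 18 h 2, pool B untreated 2 and 4 d 1, and pool C 18 h 1 and 4 d 2. The labels do not say that the hashed samples of a condition came from separate animals, so p-values measure only the spread between these samples, which may be technical.

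Per the file headers and the submitters' processing notes, each deposited matrix holds UMI counts with no normalization. The notes name Cell Ranger 5.0.0, the mouse build mm10 and Seurat 3.9.9.9024. Each matrix is the filtered set of barcodes called as cells and lists 32285 genes and 16 antibody tags, which are 10 surface antibodies and 6 hashtags. A deposited table gives the mean expression in 35 clusters, in depth-corrected linear values per its file name, and a deposited note pairs each hashtag with a hashed sample. The files give no cell annotation, so clusters and their names were rebuilt here and may differ from those of the submitters.

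The pools held 10733, 5517 and 12163 barcodes, with 80378137, 71286859 and 87221162 RNA UMIs and 8950761, 7935402 and 13138049 antibody UMIs. Barcodes were assigned to hashed samples with HTODemux of Seurat 5.3.0 at the 0.99 quantile, from the 2 hashtags of each pool. HTODemux was run on values transformed per cell with k-means clustering, because its default setting left 6064 barcodes of pool A without a call. That choice was made after the data were examined. Barcodes positive for both hashtags numbered 732, 295 and 974, and barcodes positive for none 43, 76 and 232. Doublets within a hashed sample were called with Scrublet in scanpy 1.11.5, which marked 264, 150 and 446 barcodes. The automatic threshold of 0.621 in pool A marked 0 barcodes, so the mean of the thresholds of pools B and C, 0.219, was used there. Scrublet marked 26.1%, 31.3% and 30.1% of the hashtag doublets, so doublets within a hashed sample remain. Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, which left 23772 cells.

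Cells were clustered on 1926 of the 2000 most variable genes with 20 principal components, 15 neighbours and the Leiden method at resolution 1.2 (leidenalg 0.10.2). This gave 34 clusters, and splitting 1 cluster into cells with ILC2 markers and cells with basophil or mast cell markers gave 35. Clusters were named from 26 lists of cell type markers when at least 3 markers were detected in at least 10% of the cells with a log2 fold of at least 1 over the other cells, with a pseudocount of 20 CPM. Each named class is called by its cell type with "-like" understood. The ranking rule, the split and a joint class of thymocytes and γδ T cells were set after the clusters were examined. The 18 named classes hold all cells but 537, which fell in 4 unnamed clusters. Unnamed cells made up 2 and 6 cells in the untreated samples, 112 and 304 at 18 h, and 10 and 103 at 4 d.

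Thymocyte-like cells of different conditions lay in different clusters. Clusters 0, 1, 4, 5, 13 and 15 held most of them at 18 h, clusters 3, 6, 9 and 10 in the untreated samples, and clusters 3, 9 and 12 at 4 d. The rebuilt clusters were set beside the deposited averages by correlation over 2000 genes, which are not independent replicates. The best correlation of a rebuilt cluster ranged upward from 0.537 with a median of 0.914, and 29 of the 35 deposited clusters were the best match of at least 1 rebuilt cluster.

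The gene lists, marker lists, tests, alternatives and the rule for named genes were chosen before the data were examined. Cell numbers per class were compared with the quasi-likelihood test of edgeR 4.0.16, offset by all cells of the hashed sample. UMI counts were summed per hashed sample and class and compared with the same test after TMM normalization and filterByExpr. Classes with at least 20 cells in every hashed sample were tested, which left thymocyte-like, B cell-like and mature αβ T cell-like cells, besides the sum of all cells. One model with the 3 conditions left 3 residual degrees of freedom, and 1 with the pool as a block. Adjusted p-values are Benjamini-Hochberg values, over classes or over genes within a class and contrast, and calls were made at 0.05. Permuting 2 against 2 samples cannot give a two-sided p under 0.333, so no exact test of single values can pass. Log2 folds are edgeR coefficients, their standard errors are the fold over the square root of F, and levels are edgeR CPM values with TMM factors, as mean ± SD over the 2 hashed samples.

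For each class and each contrast with the untreated samples, the 5 largest rises and 5 largest falls were named. The rule asked for an adjusted p under 0.05, a mean of at least 20 CPM and the same direction in every pairing of samples. It left out immunoglobulin and T cell receptor segments, mitochondrial and ribosomal protein genes, Gm and Rik models and the thymocyte transcripts. Members of a fixed list were named as well. The 15 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. They hold glucocorticoid receptor targets, type 2 cytokines and alarmins, alternatively activated macrophage genes, uptake and lysosome genes, cholesterol efflux genes, inflammatory genes, interferon-stimulated genes, regeneration factors, cell cycle genes, MHC class II genes, apoptosis and p53 genes, immediate early genes, hypoxia genes, chemokine receptors and thymocyte transcripts. The thymocyte transcripts were chosen to measure RNA of lysed thymocytes in other cells. Of the list members kept by the filter on low counts, none was at 0 UMIs in both samples of a condition in the classes tested. Members without counts were not tested, such as Il25, with 0 UMIs in 14813 thymocyte-like cells. Counts of genes with near-identical copies, such as Ifit3, Ly6c2 and histone genes, may be split between the copies and are uncertain. Antibody counts were averaged per class and hashed sample, centred over the 10 antibodies on the log2 scale with a pseudocount of 0.01, and compared with limma.

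The tests were tested on simulated data built from these samples. For B cell-like cells at 18 h, 28% of genes changed by a log2 fold of 1 and 87% of those changed by 2 were called, and 9.45% of calls were false. For mature αβ T cell-like cells at 18 h the values were 14%, 76% and 3.23%. For thymocyte-like cells at 18 h they were 71%, 88% and 11.2%. The list test called 8 of 8 raised lists and 0 of 8 unchanged lists, at the preset correlation and by unadjusted p-values. With an estimated correlation it was not scored, so its power is not known. The share test called 3 of 3 raised classes and 0 of 15 others. Each simulation changed 100 genes at each size, up and down in equal number, of 13683 in thymocyte-like cells. These are far fewer than edgeR called there in the data at 18 h. False calls and TMM normalization were thus not tried on changes that wide. Genes were simulated independently of each other, so the list test was not tried on correlated genes. Class shares were simulated with a fixed dispersion and not with the spread of these samples.

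Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, the pool or the replicate number as a block, each hashed sample left out, a filter of 500 genes and 5% mitochondrial UMIs, hashtag calls from a Gaussian mixture with a posterior of 0.95 (mclust 6.1.1), doublets kept, UMIs thinned to 1 total, the share of cells other than thymocyte-like ones, TMM factors over classes, limma on logit shares, and Leiden resolution 0.6 on 30 components. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3. Shares of single samples carry 95% Wilson intervals, a count of 0 allows up to 3 counts, and both cover counting error only. Coordinates are 1-based on GRCm38 (mm10) from GENCODE vM21, matched by Ensembl gene ID.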

Results

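Messenger RNA and 10 surface proteins were counted in single thymus cells of untreated mice and of mice given dexamethasone 18 h or 4 days earlier, with 2 hashed samples per condition. After filtering, untreated sample 1 held 2369 cells with 30190214 RNA UMIs and untreated sample 2 held 2385 cells with 38576346. The 18 h samples held 4429 cells with 21850528 UMIs and 6537 cells with 39693401. The 4 d samples held 2340 cells with 25591423 UMIs and 5712 cells with 51431602. The median UMIs per cell were 12195 and 15755 in the untreated samples, 4266 and 4955 at 18 h, and 8094 in sample 2 and 10243 in sample 1 at 4 d. Cells were sorted before loading and mature T cells were gated out, so shares describe the sorted cells and not the whole thymus. The 2 samples of a pool shared 1 library, and values within a pool compare 1 sample with 1 sample, without replicates.

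The first comparison asked which cell classes filled the thymus 18 h after dexamethasone. Neutrophil-like cells, first responders to tissue damage that carry S100a8 and Ngp, rose from 0.42% ± 0.295 (SD, n = 2) of cells to 3.22% ± 1.23 (SD, n = 2). Mature αβ T cell-like cells fell from 4.37% ± 2.00 to 0.785% ± 0.00712. In this class Rag1, a gene of immature thymocytes, stood at 809.6 and 365.8 CPM in the untreated samples, without TMM factors, and at 24.04 and 46.3 at 18 h. Thymocyte-like cells, which here include γδ T cells, made up 86.9% ± 4.79 of untreated and 82.9% ± 3.23 of 18 h cells. Macrophage-like cells, marked by the complement genes C1qa, C1qb and C1qc, made up 0.526% ± 0.0867 and 1.75% ± 0.272, and NK cell or ILC1-like cells 0.82% ± 0.145 and 0.268% ± 0.163. By edgeR's test, 2 of the 18 classes passed, with log2 folds of 2.93 (SE 0.61, adjusted p = 0.00773) for neutrophil-like and -2.47 (SE 0.51, adjusted p = 0.00773) for mature αβ T cell-like cells. The other classes named did not pass, with adjusted p = 0.785 for thymocyte-like, 0.0787 for macrophage-like and 0.0946 for NK cell or ILC1-like cells by edgeR. Among cells other than thymocyte-like ones, the NK cell or ILC1-like share passed as well (-2.02, edgeR adjusted p = 0.0247). Within pool A, the log2 ratio of 18 h sample 2 to untreated sample 1 was 4.27 for neutrophil-like and -1.92 for mature αβ T cell-like cells. With the pool as a block 0 classes passed, without 18 h sample 2 also 0, without 18 h sample 1 the neutrophil-like class alone, and without untreated sample 2 the count was 9.

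The second comparison asked how the thymus differed from the untreated state 4 d after dexamethasone. Dendritic cells, which present antigen to T cells, made up a large part of the cells, and thymocytes a smaller part. Thymocyte-like cells fell to 21.4% ± 3.84 (SD, n = 2) of cells, a log2 fold of -2.02 (SE 0.21, edgeR adjusted p = 2.99e-05). A class of conventional dendritic cells whose subset was not named was led by S100a4, Tbc1d4, Ifi30 and Cldn1. It rose from 0.0839% ± 0.119 to 30.1% ± 3.30, a log2 fold of 8.43 (SE 0.66, edgeR adjusted p = 6.4e-06). The untreated samples held 0 and 4 of these cells, and 3 and 17 cDC1-like cells, so the sizes of both folds are uncertain. The cDC1-like cells, marked by Xcr1 and Clec9a and known for cross-presentation, rose from 0.42% ± 0.414 to 11.9% ± 3.16, a log2 fold of 4.82 (SE 0.67, edgeR adjusted p = 0.00025). Activated (Ccr7+) DC-like cells rose from 0.672% ± 0.532 to 5.60% ± 0.719, with an edgeR adjusted p = 0.00167.

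Lymphoid, myeloid and stromal classes rose as shares of all cells as well. B cell-like cells rose from 4.31% ± 0.604 (SD, n = 2) to 10.651% ± 0.0147, a log2 fold of 1.30 with edgeR adjusted p = 0.005. Plasma cell-like cells, which secrete antibody, rose from 0.21% ± 0.0605 to 3.42% ± 0.608 (log2 fold 4.01, edgeR adjusted p = 0.000325). ILC2-like cells, innate lymphocytes that make type 2 cytokines, rose from 0.147% ± 0.0899 to 1.48% ± 0.215 (log2 fold 3.31, edgeR adjusted p = 0.00336). NK cell or ILC1-like cells rose to 2.96% ± 0.496 with edgeR adjusted p = 0.013, neutrophil-like cells to 4.30% ± 1.07 with 0.00128 and monocyte-like cells from 0.252% ± 0.118 to 1.94% ± 1.24 with 0.013. Fibroblast-like cells rose from 0.105% ± 0.148 to 1.55% ± 0.341 with edgeR adjusted p = 0.005. The untreated samples held only 6 and 4 plasma cell-like, 5 and 2 ILC2-like and 0 and 5 fibroblast-like cells, so the sizes of these rises are uncertain. Fibroblasts, endothelial and epithelial cells are not haematopoietic and lie outside the sort's gate. Endothelial-like and thymic epithelial-like cells were not found among the 2369 and 2385 untreated cells, which allows shares of up to 0.127% and 0.126%, and made up 1.08% ± 0.746 and 0.552% ± 0.186 at 4 d, with edgeR adjusted p = 0.00335 and 0.00704. Macrophage-like cells fell to 0.104% ± 0.0262, a log2 fold of -2.24 (SE 0.71, edgeR adjusted p = 0.0136), and mature αβ T cell-like cells to 0.799% ± 0.139 (log2 fold -2.46, edgeR adjusted p = 0.00253). Plasmacytoid DC-like cells made up 0.232% ± 0.15 and 0.113% ± 0.0386, eosinophil-like cells 0.335% ± 0.474 and 0.816% ± 0.115, and neither passed, nor did basophil or mast cell-like cells.

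In all, 15 of the 18 classes passed at 4 d, 12 upward and 3 downward. With Leiden resolution 0.6 on 30 components 13 passed and the thymocyte-like call was lost (log2 fold -0.68, edgeR adjusted p = 0.0959). There, a cluster of 1725 cells led by Lef1, Dut and Cdca7, leading genes of thymocyte-like cluster 6, was named mature αβ T cell, and 1 of 1015 cells led by Hist1h1b and Sh2d1a was not named. In the same clustering ILC2-like cells were not separate, and the cluster led by S100a4 and Nccrp1, of 2575 cells, was named cDC2. Within pool B, the log2 ratio of 4 d sample 1 to untreated sample 2 was -1.79 for thymocyte-like, 7.60 for the unnamed dendritic, 3.76 for cDC1-like, 1.17 for B cell-like, 1.499 for NK cell or ILC1-like, 3.98 for ILC2-like and -2.78 for macrophage-like cells. With the pool as a block 9 classes passed, and the B cell-like, ILC2-like, NK cell or ILC1-like, macrophage-like, monocyte-like and thymic epithelial-like classes no longer did. Among cells other than thymocyte-like ones, 6 classes passed. Of the 3 dendritic classes, the unnamed one (5.91) and cDC1-like cells (2.30) stayed higher, while activated (Ccr7+) DC-like cells did not pass (0.54, edgeR adjusted p = 0.372), and B cell-like (-1.33), macrophage-like (-4.81), mature αβ T cell-like (-5.04) and plasmacytoid DC-like (-3.60) shares were lower. The macrophage-like call was lost without either 18 h sample, without either 4 d sample and with the stricter cell filter. It was lost for NK cell or ILC1-like cells without either 4 d sample, for ILC2-like and monocyte-like cells without 4 d sample 2, and for thymic epithelial-like cells without 4 d sample 1. Cells with at least 20 UMIs of the C1q genes made up 0.316% of untreated, 0.793% of 18 h and 0.534% of 4 d cells, and 29 of the 43 such cells at 4 d lay in the monocyte-like cluster. With at least 5 such UMIs and 0.5% of the cell's UMIs, the shares were 0.568%, 1.31% and 0.248%. The cells of the first rule had median depths of 3349, 2831 and 12114 UMIs.

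The third comparison set 4 d against 18 h. Of the 18 classes, 12 passed in edgeR's test, 10 upward and 2 downward. Macrophage-like cells fell by 3.97 on the log2 scale (SE 0.67, edgeR adjusted p = 0.000715) and thymocyte-like cells by 1.95 (adjusted p = 3.89e-05). The unnamed dendritic class rose by 6.29, cDC1-like cells by 4.41, NK cell or ILC1-like cells by 3.49 (edgeR adjusted p = 0.000773), plasma cell-like cells by 3.08, ILC2-like cells by 2.82 and B cell-like cells by 1.72 (edgeR adjusted p = 0.00122). Neutrophil-like cells differed by a log2 fold of 0.42 (edgeR adjusted p = 0.487). As a share of cells other than thymocyte-like ones, they fell from 18.5% ± 3.69 to 5.45% ± 1.09. That log2 fold was -1.76 (edgeR adjusted p = 0.000196), so the direction turns with the cells counted. Within pool C, the log2 ratio of 4 d sample 2 to 18 h sample 1 was -3.67 for macrophage-like, 6.26 for the unnamed dendritic, 4.97 for cDC1-like, 3.11 for NK cell or ILC1-like and 1.64 for B cell-like cells. With the pool as a block 6 classes passed, and the B cell-like, ILC2-like, activated (Ccr7+) DC-like, endothelial-like, fibroblast-like and monocyte-like calls were lost. Among cells other than thymocyte-like ones the call was lost for B cell-like (-0.51), NK cell or ILC1-like (1.25), plasma cell-like (0.87) and ILC2-like cells (0.64). It was also lost there for activated (Ccr7+) DC-like (0.51), endothelial-like (0.91), fibroblast-like (0.017) and monocyte-like cells (0.10). Mature αβ T cell-like (-2.21) and plasmacytoid DC-like shares (-3.90) passed downward there, as did the neutrophil-like share. For ILC2-like cells the call was also lost without 18 h sample 1, 4 d sample 1 or 4 d sample 2.

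**Figure D1:**
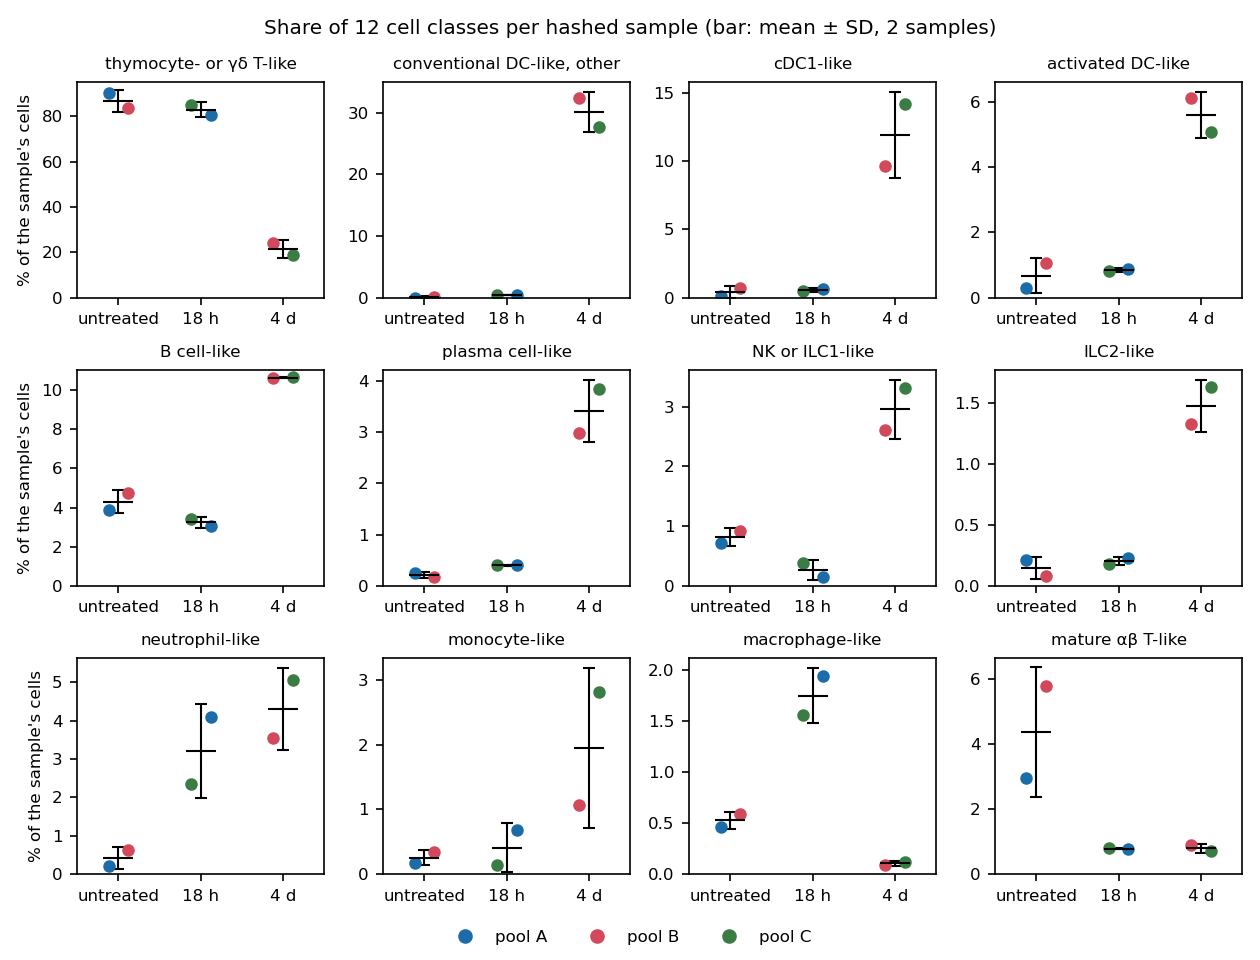
Share of 12 cell classes in percent of the sample's cells, with 1 panel per class, the conditions on the horizontal axis, a dot per hashed sample coloured by pool, and bars at the mean with SD over 2 samples. Thymocyte-like cells lie at 21.4% on average at 4 d, the unnamed dendritic class at 30.1%.

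Within thymocyte-like cells, 18 h after dexamethasone, 14 of 15 glucocorticoid targets and all 15 interferon-stimulated genes rose, and all 18 cell cycle genes fell. For each of these lists camera gave adjusted p = 0.336 with an estimated correlation. Fst, which encodes the activin antagonist follistatin (chromosome 13, 114452290 to 114458951, minus strand, ENSMUSG00000021765), rose from 0.411 ± 0.459 to 113 ± 37.6 CPM (SD, n = 2). Its log2 fold was 8.18 (SE 0.67, edgeR adjusted p = 1.6e-05). M1ap rose by a log2 fold of 7.92, Neb, the gene of the muscle protein nebulin (chromosome 2, 52136647 to 52378474, minus strand, ENSMUSG00000026950), by 7.58, Trnp1 by 7.48 and Scrg1 by 7.47. Pclaf, which encodes a PCNA-binding replication factor (chromosome 9, 65890237 to 65903266, plus strand, ENSMUSG00000040204), fell from 681 ± 24.7 to 32.1 ± 1.36 CPM, a log2 fold of -4.41 (SE 0.12, edgeR adjusted p = 4.5e-07). Cdc6 (-4.34) and Ccne2 (-4.14), which act at the start of DNA replication, Rrm2 (-4.32), a subunit of ribonucleotide reductase, and Nebl (-4.19) fell as well. The edgeR test called 9135 of 13683 genes, 4862 upward and 4273 downward. Clusters 0, 1, 4, 5, 13 and 15 held most thymocyte-like cells at 18 h and clusters 3, 6, 9 and 10 most in the untreated samples, so these values set different thymocyte states side by side. All folds are relative to the RNA total. Over all cells, median UMIs per cell were 12195 and 15755 untreated and 4266 and 4955 at 18 h. A rise in CPM therefore need not be a rise per cell. Tnfsf11 stood at 52.0 CPM untreated and 143 at 18 h, without TMM factors. It was seen in 34.1% and 30.3% of thymocyte-like cells.

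Of the glucocorticoid receptor targets, 14 of 15 measured members rose, and 14 when adjusted over the list alone, with a median log2 fold of 3.32 (camera adjusted p = 3.6e-05). The adjusted p was 0.336 with an estimated correlation. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose from 65.81 and 88.13 CPM in the 2 untreated samples to 846.6 and 885.7 at 18 h (log2 fold 3.49), and Fkbp5 (1.66), Zbtb16 (6.68) and Mt1 (6.17) rose with it. All 15 measured interferon-stimulated genes rose, and 15 when adjusted over the list alone, with a median of 4.67, among them Isg15 (4.44), Ifit1 (6.47) and Stat1 (3.102), with camera adjusted p = 3.7e-07 and adjusted p = 0.336 with an estimated correlation. All 18 cell cycle genes fell, and 18 when adjusted over the list alone, with a median of -1.99, camera adjusted p = 2.3e-08 and adjusted p = 0.336 with an estimated correlation. Inflammatory genes rose in 8 of 13 (8 when adjusted over the list alone), Cxcl10 (3.55) and Tnfaip3 (2.14) among them, with a median of 1.56, camera adjusted p = 0.044 and adjusted p = 0.336 with an estimated correlation. Immediate early genes rose in 12 of 16, with a median of 1.36, camera adjusted p = 0.0084 and adjusted p = 0.378 with an estimated correlation. The camera test did not call the other 10 lists. Among these, 10 of 14 apoptosis and p53 genes rose and 3 fell (camera adjusted p = 0.072). Bcl2l11 (2.21) and Bmf (3.74), which encode death-promoting proteins, rose, as did Bcl2 (2.98), which encodes a survival protein, while Casp3 (-2.16) fell. Type 2 genes rose in 6 of 10 and fell in 2, with Areg (3.76) and Il4ra (3.82) highest, and hypoxia genes rose in 1 of 13 and fell in 7. Chemokine receptors rose in 7 of 14 and fell in 2, alternatively activated macrophage genes rose in 3 of 6, MHC class II genes in 5 of 12, uptake genes in 5 of 10 with 1 fall, cholesterol efflux genes in 5 of 13 with 1 fall, and regeneration factors in 7 of 11 with 2 falls. Thymocyte transcripts rose in 5 of 17 and fell in 10.

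At 4 d, Fst, Gimap3, Lgals3, S100a6 and Itgae were the largest named rises in thymocyte-like cells, and Id3 and Lef1 the largest named falls. Gimap3, of a GTPase family active in lymphocyte survival (chromosome 6, 48764464 to 48770851, minus strand, ENSMUSG00000039264), rose from 0.526 ± 0.048 to 73.4 ± 16.99 CPM (SD, n = 2), a log2 fold of 7.10 (SE 0.33, edgeR adjusted p = 1.1e-05). Fst (7.20), Lgals3 (6.21), S100a6 (6.08) and Itgae (5.92), the integrin chain that binds E-cadherin, rose by similar sizes. Id3 (-3.77), an inhibitor of E proteins downstream of the pre-T cell receptor, Lef1 (-3.71), a transcription factor of T cell development, Spats2 (-3.30), Cd81 (-3.29) and Camk4 (-2.72) fell. Of 13683 genes, edgeR called 4924, 2691 upward and 2233 downward. It called 2799 without untreated sample 1 and 2631 without untreated sample 2. Clusters 3, 9 and 12 held most of these cells at 4 d, and cluster 12 has γδ T cell genes such as Tcrg-C4 and Trdc among its leading genes.

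The camera test called 10 lists in thymocyte-like cells at 4 d. Chemokine receptors rose in 9 of 14 (10 when adjusted over the list alone), with a median of 1.58, camera adjusted p = 0.00028 and adjusted p = 0.227 with an estimated correlation. S1pr1, the receptor for thymic exit (5.81), Ccr7 (3.46) and Sell (1.27) were among them. Regeneration factors rose in 8 of 11 and fell in 1 (8 up and 2 down when adjusted over the list alone), with a median of 1.78, camera adjusted p = 0.0045 and adjusted p = 0.227 with an estimated correlation. Type 2 genes rose in 6 of 10, with a median of 1.18, camera adjusted p = 0.0028 and adjusted p = 0.227 with an estimated correlation. They include Areg (3.32), which encodes the growth factor amphiregulin, Il4ra (2.93), Ccr4 (2.31) and Gata3 (0.43). Glucocorticoid targets rose in 11 of 15 (12 when adjusted over the list alone), with a median of 1.48, camera adjusted p = 0.00014 and adjusted p = 0.227 with an estimated correlation. Interferon-stimulated genes rose in 13 of 15, with a median of 2.02, and cell cycle genes fell in 15 of 18, with a median of -1.17, at camera adjusted p = 4.9e-06 and 1.4e-07, and for both adjusted p = 0.334 with an estimated correlation. Immediate early genes rose in 10 of 16, inflammatory genes in 6 of 13 and MHC class II genes in 4 of 12 (3 when adjusted over the list alone), with camera adjusted p = 0.0045, 0.0045 and 0.0098, and with adjusted p = 0.489, 0.274 and 0.507 with an estimated correlation. Thymocyte transcripts rose in 1 of 17 and fell in 10, with a median of -0.40, camera adjusted p = 0.0023 and adjusted p = 0.227 with an estimated correlation.

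Between 18 h and 4 d, glucocorticoid targets fell in thymocyte-like cells in 12 of 15 (12 when adjusted over the list alone), with a median of -1.55, camera adjusted p = 0.001 and adjusted p = 0.578 with an estimated correlation. Interferon-stimulated genes fell in 14 of 15 (14 when adjusted over the list alone), with a median of -2.54, camera adjusted p = 1.9e-06 and adjusted p = 0.578 with an estimated correlation. Cell cycle genes rose in 13 of 18 (13 when adjusted over the list alone), with a median of 1.08, camera adjusted p = 0.00063 and adjusted p = 0.64 with an estimated correlation. In this contrast, edgeR called 6873 of 13683 genes, 3496 upward and 3377 downward.

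In B cell-like cells, 18 h after dexamethasone, 7 of 12 glucocorticoid targets and 7 of 13 interferon-stimulated genes rose, and 5 of 12 MHC class II genes fell. For these lists camera gave adjusted p = 0.368, 0.412 and 0.419 with an estimated correlation. Fkbp5, a chaperone gene induced by the glucocorticoid receptor (chromosome 17, 28399094 to 28517527, minus strand, ENSMUSG00000024222), rose from 34.85 and 26.15 CPM in the untreated samples to 192.6 and 324.5 at 18 h, a log2 fold of 3.16 (SE 0.32, edgeR adjusted p = 0.0012). Tsc22d3 (1.66), Dusp1 (1.47) and Cdkn1a (4.19) rose as well, and free RNA predicts 67.8% of the Cdkn1a rise. The profile of free RNA was not limited to thymocytes. Il4i1, which encodes an amino acid oxidase induced by interleukin 4 (chromosome 7, 44816387 to 44840809, plus strand, ENSMUSG00000074141), fell from 146 ± 54.7 to 25.3 ± 5.65 (SD, n = 2), a log2 fold of -2.62 (SE 0.34, edgeR adjusted p = 0.0022). Egr2 (-1.98), a gene of antigen receptor signalling, Ly6k (-2.84), Cacna1d (-2.18) and Arhgap6 (-1.98) fell too. In B cell-like cells, edgeR called 276 of 8192 genes, 179 upward and 97 downward. It called 101 without untreated sample 1, 46 without untreated sample 2, 146 without 18 h sample 2 and 428 with the pool as a block.

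Of the 5 largest named rises in B cell-like cells at 18 h, Col27a1, Neb and Ldhd are also leading genes of thymocyte-like clusters of that time. Free RNA predicts 57.5% of the rise of Sytl3, 47.5% of Ldhd, 43.8% of Neb, 32.6% of Col27a1 and 28.9% of Il7r. Col27a1, a collagen gene, had 0 UMIs in untreated and 190 in 18 h B cell-like cells, at least 49.1-fold higher against 3 UMIs over the group. Neb had 3 and 134 UMIs, a ratio of 34.6 (exact interval 11.6 to 170.04), and Sytl3 2 and 103 UMIs, a ratio of 39.9 (10.8 to 334.1). Il7r (4.92), the interleukin 7 receptor gene, and Ldhd (4.26) followed. At 18 h, Col27a1 stood at 96.7 CPM, without TMM factors, in B cell-like, 479.8 in thymocyte-like and 31.4 in neutrophil-like cells, and Neb at 70.6, 460.5 and 23.7. In B cell-like cells, the median level of thymocyte transcripts relative to the pool was 5.38% and 10.0% in the untreated samples, 22.7% and 22.3% at 18 h, and 3.28% and 6.404% at 4 d. This list rose in 3 of 14 at 18 h (3 when adjusted over the list alone), with a median of 0.63, camera adjusted p = 0.01 and adjusted p = 0.511 with an estimated correlation. Without the 32 rises that free RNA predicts by at least 50%, Sytl3 among them, an alternative chosen after the data were seen, 244 calls were left.

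**Figure D2:**
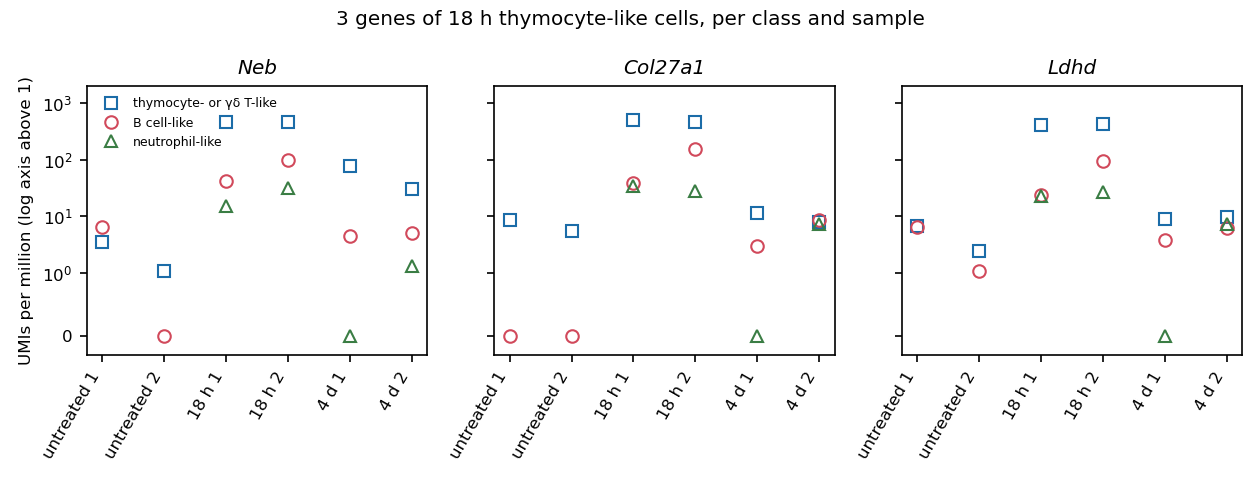
CPM, without TMM factors, of 3 genes that lead the thymocyte-like clusters of 18 h, per cell class and hashed sample, on an axis that is linear below 1 and logarithmic above. At 18 h, Neb stands at 42.4 and 98.7 in B cell-like cells and at 457.0 and 463.99 in thymocyte-like cells.

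Among the fixed lists, glucocorticoid targets rose in 7 of 12 in B cell-like cells at 18 h (10 when adjusted over the list alone), with a median of 2.01, camera adjusted p = 2.4e-07 and adjusted p = 0.368 with an estimated correlation. Interferon-stimulated genes rose in 7 of 13 (11 when adjusted over the list alone), with a median of 1.02, camera adjusted p = 3.2e-08 and adjusted p = 0.412 with an estimated correlation. Ifit3 (2.32), Isg15 (1.73) and Rsad2 (2.39), antiviral effectors, rose, while Stat1 differed by 0.04. MHC class II genes fell in 5 of 12 (8 when adjusted over the list alone), with a median of -0.45, camera adjusted p = 0.0024 and adjusted p = 0.419 with an estimated correlation. H2-Ab1 fell from 3908 and 4105 CPM in the untreated samples to 2820 and 2064 at 18 h (-0.72), with H2-Aa (-0.64), Cd74 (-0.44), the invariant chain, and Ifi30 (-0.86). Apoptosis and p53 genes rose in 5 of 13 (5 up and 1 down when adjusted over the list alone), Bcl2l11 (1.80) and Bcl2 (1.09) among them, with camera adjusted p = 0.0091 and adjusted p = 0.368 with an estimated correlation. Cholesterol efflux genes rose in 1 of 11 (1 when adjusted over the list alone), with a median of 0.43, camera adjusted p = 0.0015 and adjusted p = 0.412 with an estimated correlation. The gene was Plin2 (2.01), and free RNA predicts 66.0% of its rise. At 18 h Plin2 stood at 268 CPM, without TMM factors, in neutrophil-like and 102 in thymocyte-like cells. Inflammatory genes had 0 of 6 called (1 when adjusted over the list alone), with a median of 0.78, camera adjusted p = 0.023 and adjusted p = 0.511 with an estimated correlation. Cell cycle genes had 0 of 17 called, with a median of -0.28 and camera adjusted p = 0.74 upward, so that the median and the test differ in sign.

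At 4 d, fewer genes of B cell-like cells differed from the untreated level, with 0 of 17 cell cycle genes called and 2 of 13 interferon-stimulated genes lower. Both lists were called downward by camera, with adjusted p = 0.474 with an estimated correlation for both. Atf3, a stress-induced transcription factor gene (chromosome 1, 191170296 to 191218039, minus strand, ENSMUSG00000026628), rose from 28.2 ± 6.12 to 149 ± 7.58 CPM (SD, n = 2), a log2 fold of 2.47 (SE 0.21, edgeR adjusted p = 0.00044). Lyz2 (2.73), the lysozyme gene of myeloid cells, Lmna (2.52), Hs3st1 (2.27) and Ildr1 (2.21) rose. Aire, the regulator of tissue antigen expression that thymic B cells can carry, fell from 40.7 ± 8.32 to 12.03 ± 1.54 CPM, a log2 fold of -1.77 (SE 0.29, edgeR adjusted p = 0.0227). Ly6c2 fell from 998 ± 63.6 to 335 ± 18.4 (-1.58), and Pclaf (-2.02), Sox4 (-1.96) and Slfn1 (-1.87) fell too. Of 8192 genes, edgeR called 61, 41 upward and 20 downward, 34 without 4 d sample 1, 34 without 4 d sample 2, 0 without untreated sample 2 (792 at unadjusted p below 0.05), 172 without 18 h sample 1, 201 without 18 h sample 2, and 332 with the pool as a block.

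Cholesterol efflux genes rose in 4 of 11 in B cell-like cells at 4 d (6 when adjusted over the list alone), with a median of 0.86, camera adjusted p = 1.2e-07 and adjusted p = 0.422 with an estimated correlation. They were Abca1 (1.27), which exports cholesterol, Apoe (0.78), Apoc1 (3.77) and Scd1 (1.24), a desaturase. Apoc1 also leads the macrophage-like cluster, and the myeloid gene Lyz2 rose by 2.73 in the same cells. Surface CD11b, a myeloid integrin, averaged 9.18 counts in untreated and 25.6 in 4 d B cell-like cells (limma adjusted p = 0.309, and 0.0025 with values centred per cell). Interferon-stimulated genes fell in 2 of 13 (9 when adjusted over the list alone), Usp18 (-1.23) and Bst2 (-0.96), with a median of -0.96, camera adjusted p = 1.5e-09 and adjusted p = 0.474 with an estimated correlation. Cell cycle genes had 0 of 17 called (14 downward when adjusted over the list alone), with a median of -1.35, camera adjusted p = 4.3e-06 and adjusted p = 0.474 with an estimated correlation. Chemokine receptors rose in 2 of 10 (3 up and 1 down when adjusted over the list alone), S1pr1 (1.25) and Cxcr4 (1.01), with camera adjusted p = 0.046 and adjusted p = 0.54 with an estimated correlation. Hypoxia genes fell in 1 of 10 (1 up and 4 down when adjusted over the list alone), with a median of -0.45, camera adjusted p = 0.0057 and adjusted p = 0.422 with an estimated correlation. MHC class II genes had 0 of 12 called (2 when adjusted over the list alone), with a median of 0.16, camera adjusted p = 0.021 and adjusted p = 0.526 with an estimated correlation. Thymocyte transcripts rose in 1 of 14 and fell in 1 (1 up and 8 down when adjusted over the list alone), with a median of -1.62, camera adjusted p = 0.00012 and adjusted p = 0.474 with an estimated correlation. Glucocorticoid targets had 0 of 12 called (2 when adjusted over the list alone), with a median of 0.77, camera adjusted p = 0.0496 and adjusted p = 0.526 with an estimated correlation, and camera adjusted p = 0.00045 with the pool as a block.

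From 18 h to 4 d, all 13 measured interferon-stimulated genes fell in B cell-like cells (13 when adjusted over the list alone), with a median of -1.97, camera adjusted p = 3.0e-18 and adjusted p = 0.275 with an estimated correlation. MHC class II genes rose in 7 of 12 (12 when adjusted over the list alone), with a median of 0.65, camera adjusted p = 5.1e-08 and adjusted p = 0.275 with an estimated correlation. Cd86 (0.95) and Cd40 (1.01), costimulatory molecules, rose with H2-Aa (0.74) and H2-Ab1 (0.82). Glucocorticoid targets fell in 5 of 12 (6 when adjusted over the list alone), with a median of -1.18, camera adjusted p = 6.7e-05 and adjusted p = 0.275 with an estimated correlation. Cell cycle genes fell in 6 of 17 (10 when adjusted over the list alone) and inflammatory genes in 2 of 6 (3 when adjusted over the list alone), with camera adjusted p = 4.7e-06 and 0.0051, and for both adjusted p = 0.389 with an estimated correlation. Thymocyte transcripts fell in 10 of 14 (13 down and 1 up when adjusted over the list alone), with a median of -1.77, camera adjusted p = 5.1e-08 and adjusted p = 0.275 with an estimated correlation. The edgeR test called 521 of 8192 genes, 221 upward and 300 downward, and fewer without 18 h sample 2 (288), without 4 d sample 1 (278) and without 4 d sample 2 (263).

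Mature αβ T cell-like cells, a class of 21 to 138 cells per sample that the sort was meant to leave out, differed at both times, with S1pr1 and Gimap3 higher and Id3 and Endou lower at 4 d. Rag1 stood at 809.6 and 365.8 CPM in its untreated samples, without TMM factors, against 199.3 and 147.7 in untreated thymocyte-like cells, and at 24.04 and 46.3 at 18 h. These values thus set cells of different states side by side. S1pr1, the sphingosine receptor that lets T cells leave the thymus (chromosome 3, 115710433 to 115715072, minus strand, ENSMUSG00000045092), rose from 5.42 ± 4.34 to 292.06 ± 98.8 CPM (SD, n = 2) at 4 d, a log2 fold of 6.10 (SE 0.67, edgeR adjusted p = 0.00035). At 4 d Gimap3 (5.88) rose, Itgb7, an integrin chain of gut homing, had 3 UMIs in untreated and 54 in 4 d cells, a ratio of 82.7 (exact interval 26.8 to 413), and Igfbp4 had 3 and 35, a ratio of 53.6 (16.9 to 272). Id3 (-3.78), Endou (-3.58), Ldhb (-3.11) and Ptov1 (-2.74) fell at 4 d. At 18 h, Ly6d, a surface protein of early lymphocytes (chromosome 15, 74762056 to 74763620, minus strand, ENSMUSG00000034634), fell from 927 ± 303 to 71.4 ± 42.0, a log2 fold of -3.78 (SE 0.52, edgeR adjusted p = 0.00089). Cbfa2t3 had 103 UMIs in untreated and 0 in 18 h cells, at least 5.07-fold lower. Neb had 0 UMIs in untreated and 31 in 18 h cells, at least 70.0-fold higher, and 16 in 4 d cells, at least 24.5-fold higher. Thymocyte-like cells hold Neb at 460.5 CPM, without TMM factors, at 18 h.

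The interferon-induced genes Ifi213 (5.50) and Oas3, with 3 and 21 UMIs and a ratio of 47.4 (14.2 to 248), rose in mature αβ T cell-like cells at 18 h. Interferon-stimulated genes rose in 9 of 10 (10 when adjusted over the list alone), with a median of 3.27, camera adjusted p = 1.3e-06 and adjusted p = 0.33 with an estimated correlation. Glucocorticoid targets rose in 5 of 7 (5 when adjusted over the list alone), with a median of 2.00, camera adjusted p = 2.4e-05 and adjusted p = 0.196 with an estimated correlation. Cell cycle genes fell in 2 of 7 (4 when adjusted over the list alone) and thymocyte transcripts in 5 of 15 (6 when adjusted over the list alone), with camera adjusted p = 0.004 and 0.0012, and for both adjusted p = 0.33 with an estimated correlation. At 4 d, chemokine receptors rose in 4 of 7 (4 when adjusted over the list alone), with a median of 1.90, camera adjusted p = 0.0035 and adjusted p = 0.528 with an estimated correlation. Glucocorticoid targets rose in 3 of 7 (3 when adjusted over the list alone), with camera adjusted p = 0.0035 and adjusted p = 0.436 with an estimated correlation. From 18 h to 4 d, interferon-stimulated genes fell in 2 of 10 (9 when adjusted over the list alone), with a median of -2.47, camera adjusted p = 5.1e-07 and adjusted p = 0.575 with an estimated correlation. In this class, edgeR called 342 of 2884 genes at 18 h, 143 at 4 d and 18 between the times. At 18 h it called 115 without untreated sample 2, 71 without 18 h sample 1, 181 without 18 h sample 2, 585 without 4 d sample 1 and 549 without 4 d sample 2. At 4 d it called 48 without untreated sample 2 and 313 without 4 d sample 1, and between the times from 0 without 18 h sample 1 (431 at unadjusted p below 0.05) to 199 without 4 d sample 2.

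**Figure D3:**
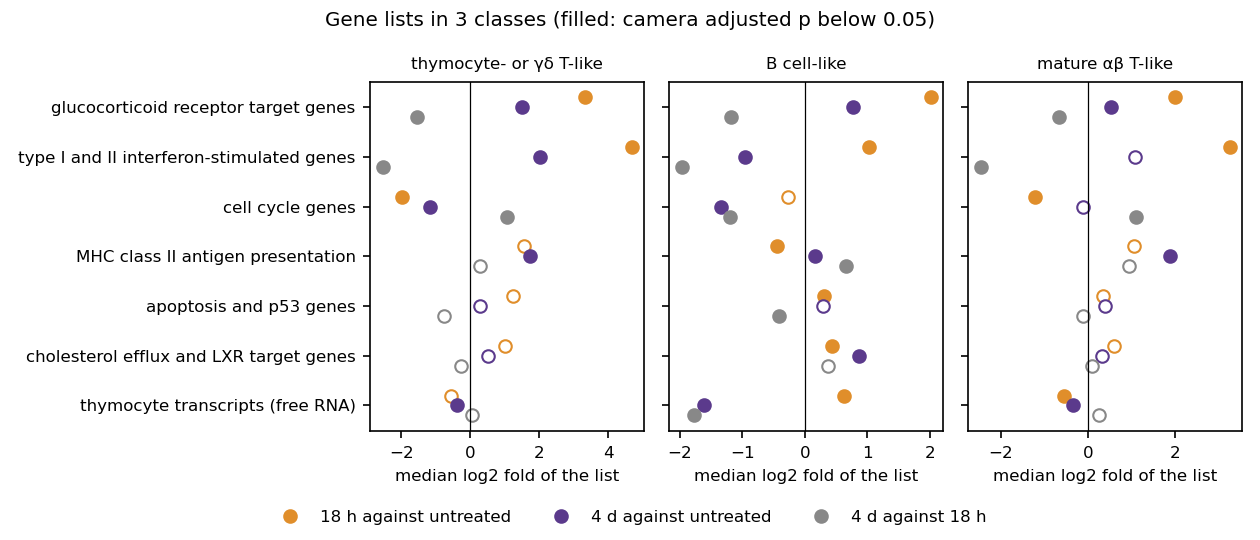
Median log2 fold of gene lists in thymocyte-like, B cell-like and mature αβ T cell-like cells. Each class has 1 panel, and colours mark the 3 contrasts. Of the 15 lists, those shown are glucocorticoid targets, interferon-stimulated, cell cycle, MHC class II, apoptosis and p53 and cholesterol efflux genes, and thymocyte transcripts. Filled points have a camera adjusted p below 0.05 at the preset correlation, and 0 of them do with an estimated correlation.

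Summed over all cells of a sample, S100a4 rose at 4 d from 24.3 ± 24.96 to 2152 ± 438 CPM (SD, n = 2), a log2 fold of 6.46 (SE 0.89, edgeR adjusted p = 0.001). Nccrp1 (7.25) and Cldn1 (6.43), which like S100a4 lead the unnamed dendritic clusters, Fabp4 (7.50), which leads the endothelial cluster, and Pid1 (6.17) rose with it, and Lef1 (-4.69), Sh2d1a (-4.16), Syt13 (-3.94), Endou (-3.82) and Hist2h2bb (-3.28) fell. At 18 h, M1ap (7.47), Fst (7.43), Neb (7.22), Eppk1 (7.11) and Trnp1 (7.10) rose and Sh2d1a (-4.24), Nebl (-4.17), Lef1 (-3.44), Rrm2 (-3.34) and Pclaf (-3.30) fell. At 4 d all 12 MHC class II genes rose (12 when adjusted over the list alone), with a median of 4.67, and all 17 thymocyte transcripts fell (17 when adjusted over the list alone), with a median of -2.19. Their camera adjusted p was 4.0e-05 and 2.4e-07, with adjusted p = 0.341 and 0.307 with an estimated correlation. Uptake and lysosome genes rose in 15 of 16 at 4 d (15 when adjusted over the list alone), with a median of 3.22, and regeneration factors in 15 of 17 (15 when adjusted over the list alone), with a median of 2.36. Their camera adjusted p was 3.1e-05 and 0.00016, and for both adjusted p = 0.307 with an estimated correlation. Type 2 cytokines and alarmins rose in 11 of 17 at 4 d and fell in 2 (11 up and 2 down when adjusted over the list alone), with a median of 2.32, camera adjusted p = 0.0235 and adjusted p = 0.341 with an estimated correlation. Alternatively activated macrophage genes rose in 9 of 11 at 18 h (9 when adjusted over the list alone) and in 8 of 11 at 4 d (8 when adjusted over the list alone), with camera adjusted p = 0.018 and 0.035, and with adjusted p = 0.361 and 0.307 with an estimated correlation. A change in any of these sums can come from the cell makeup. Macrophage-like cells made up 0.526% of untreated, 1.75% of 18 h and 0.104% of 4 d cells. At 4 d they held 2 of 123 UMIs of Mrc1, a gene of that list, and plasma cell-like cells held 50. The edgeR test called 9564 genes of 15629 at 18 h, 10699 at 4 d and 8155 between the times, where the fit with the pool as a block called 4996. The median log2 fold of all genes at 18 h was 0.20 with TMM and 0.11 with DESeq2 size factors, and 57.5% and 51.8% of calls were upward.

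Surface proteins were compared in the 3 tested classes. The MHC class II protein I-A/I-E on B cell-like cells averaged 2226 ± 606 antibody counts in untreated samples (SD, n = 2), 1334 ± 217 at 18 h and 981 ± 102 at 4 d. Relative to the 10 antibodies, it was lower at 4 d by a log2 difference of -1.13 (SE 0.24, limma adjusted p = 0.0406). At 18 h the difference was -0.76 (limma adjusted p = 0.214, and 4.7e-10 with the median of values centred per cell). From 18 h to 4 d the difference was -0.36 (limma adjusted p = 0.787), and 0.32 with values centred per cell (adjusted p = 0.0204), which turns its direction. The integrin CD11b on thymocyte-like cells averaged 0.951 ± 0.85 counts in untreated samples and 5.39 ± 1.47 at 4 d, a log2 difference of 2.24 (SE 0.46, limma adjusted p = 0.00038). With values centred per cell it was -0.03 (adjusted p = 0.819), which turns the direction, and over all thymocyte-like cells the median count was 0 and the mean 3.17. Across classes, Ly-6G averaged 717 counts on neutrophil-like cells, Siglec-F 135 on eosinophil-like cells, CD19 122 on B cell-like cells and NK-1.1 53.7 on NK cell or ILC1-like cells, and I-A/I-E was 3414 on activated (Ccr7+) DC-like cells.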

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

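The tests in this part marked as set later were chosen after the results had been seen. The shares of B cell-like, NK cell or ILC1-like and macrophage-like cells stand out because their log2 folds against untreated have opposite signs at the 2 times, -0.41 and 1.30, -1.64 and 1.85, and 1.73 and -2.24, and edgeR's direct test of 4 d against 18 h passed. As shares of all cells, none of the 3 passed at 18 h against untreated. Among cells that are not thymocyte-like, the NK cell or ILC1-like share passed at 18 h (-2.02, edgeR adjusted p = 0.0247). The log2 folds of 4 d against 18 h were 1.72, 3.49 and -3.97. The B cell-like call was lost with the pool as a block, and among cells that are not thymocyte-like neither the B cell-like (-0.51) nor the NK cell or ILC1-like share (1.25) passed. In B cell-like cells the same rule, by camera, named the MHC class II genes (median log2 fold 0.65), the interferon-stimulated genes (-1.97) and the thymocyte transcripts (-1.77). In pool B, 24 barcodes carried at least 100 UMIs of hashtag 8, which was added to pool C alone, with a highest count of 1520. They stand out as a signal in data that the comparisons do not use, and 0 of the 24 barcodes are among the barcodes of pool C. In the other direction, 7 barcodes of pool C carried at least 100 UMIs of hashtag 7 of pool B, with a highest count of 950.

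Free RNA of dying thymocytes could raise genes in B cell-like cells at 18 h, and the prediction was written before the values were computed. It asked for 50% or more of the rise if free RNA were the cause, and for under 25% if not. Free RNA predicted a median of 33.7% of the rise for the 7 glucocorticoid targets called higher, 28.9% for the 7 interferon-stimulated genes and 30.7% for the 165 other genes. Its profile was not limited to thymocytes. For Atf3 it predicts a rise of 31.5 CPM, above the 27.3 CPM of thymocyte-like cells at 18 h. All 3 medians lie between the bounds, so the test leaves the matter undecided. Free RNA shared in a library would reach the cells of both samples of a pool alike. In pool A, B cell-like cells held thymocyte transcripts at a median of 5.38% of the pool level in untreated sample 1 and 22.3% in 18 h sample 2. The test did not use this difference, which rests on 1 pool, and did not cover doublets or RNA gained before pooling. A response of B cells to dexamethasone remains possible, since the design has the treatment as a group.

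Many class shares changed at 4 d, and loss of thymocyte-like cells alone would leave the other classes in their proportions to each other. Among cells that are not thymocyte-like, 6 classes differed, 2 upward and 4 downward. The 4 include the mature αβ T cell-like class, with Rag1 at 809.6 and 365.8 CPM, without TMM factors, in untreated samples. Its fall may itself be a loss of thymocytes. The unnamed dendritic share rose there (5.91) and the B cell-like share fell (-1.33). Loss of thymocytes alone would keep these 2 classes in proportion to each other, so their values argue against it as the whole cause. Differences between the 3 pools alone would leave no call with the pool as a block, and 9 of the 15 classes called kept theirs. This argues against pools as the whole cause for those 9, in a fit with only 1 residual degree of freedom. The B cell-like, ILC2-like, NK cell or ILC1-like, macrophage-like, monocyte-like and thymic epithelial-like classes lost their call, so pools are not excluded for them. Both predictions were written after the shares had been seen. Growth of other classes was not tested, because cell numbers per thymus were not analysed here, and the treatment remains the biological explanation that the design gives.

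The macrophage-like share was lower at 4 d than at 18 h, and cells with C1q RNA could lie in other clusters at 4 d, a test set later. Such cells made up 0.534% of 4 d cells by the rule of at least 20 UMIs, above the untreated 0.316%, and 0.248% by the rule of 0.5% of the cell's UMIs, under the untreated 0.568%. The first rule favours deep cells, with a median of 12114 UMIs at 4 d against 3349 untreated. The 2 rules disagree, and loss of macrophages in the filters was not tested, so it is open whether macrophages were lost after dexamethasone or changed their state.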

How the results depend on the processing

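Alternatives listed as added were chosen after the data had been seen, and the cause was not tested for any value below. Class shares kept direction and side of the threshold in 355 of 429 comparisons over 29 results, and named genes in 1122 of 1186 over 80. The 80 genes were picked from these data for large folds, a passing p-value and 1 direction in every pairing of samples. Their rate is therefore partly set by that choice and does not describe all genes called. The share of B cell-like cells turned direction among cells that are not thymocyte-like (-1.33 at 4 d against untreated, -0.51 against 18 h) and with TMM factors (-0.25 at 4 d against untreated), as did NK cell or ILC1-like cells among cells that are not thymocyte-like (-0.77 at 4 d against untreated). Among these cells, a rise of the dendritic shares lowers the shares of the others. Class share calls at 18 h (2) were 0 with the pool as a block, 4 with the strict filter and 0 to 9 with 1 sample left out. At 4 d against untreated (15) they were 6 among cells that are not thymocyte-like, 8 with TMM factors, 9 with the pool block and 11 to 16 with 1 sample left out. At 4 d against 18 h (12) they were 6 among cells that are not thymocyte-like, 6 with the pool block and 8 to 13 with 1 sample left out. With an estimated correlation 0 gene lists passed in any class or contrast, against 11, 12 and 6 in all cells, 5, 10 and 3 in thymocyte-like, 7, 8 and 8 in B cell-like and 7, 5 and 4 in mature αβ T cell-like cells. That variant rests on the 3 residual degrees of freedom and was not scored on simulated lists. Its lack of calls therefore does not show that the lists were unchanged. All-cell genes at 4 d against 18 h (8155) were 4996 with the pool block, and thymocyte-like genes at 4 d (4924) were 2631 to 5175 with 1 sample left out. B cell-like genes at 18 h (276) were 555 without a filter on counts, 167 with DESeq2, 428 with the pool block, 169 with mixture hashtag calls, 627 with doublets kept, 46 to 348 with 1 sample left out, and 244 in the added alternative without rises that free RNA predicts by at least 50%. At 4 d (61) they were 382 without a filter, 332 with the pool block, 117 with the strict filter, 434 with doublets kept and 0 to 201 with 1 sample left out. At 4 d against 18 h (521) they were 970 without a filter, 268 with DESeq2, 1014 with doublets kept, 338 with thinned UMIs and 263 to 591 with 1 sample left out. Mature αβ T cell-like genes at 18 h (342) were 581 without a filter, 197 thinned and 71 to 585 with 1 sample left out. At 4 d (143) they were 263 without a filter, 91 with DESeq2, 65 thinned and 48 to 313 with 1 sample left out. At 4 d against 18 h (18) they were 126 without a filter, 34 with DESeq2, 69 with the pool block, 39 with the strict filter, 78 with mixture calls, 32 thinned and 0 to 199 with 1 sample left out. With values centred per cell, the surface proteins passing were 0 (1) in thymocyte-like cells at 4 d, in B cell-like cells 1 (0) at 18 h, 2 (1) at 4 d and 1 (0) between the times, and in mature αβ T cell-like cells 1 (0) at 18 h and 1 (0) between the times. The correlations of deviations of samples with the same number were -0.073, 0.12 and -0.018 over all cells. With 2 samples per condition the deviations mirror each other, and pooled samples have unlike numbers, so these values cannot exclude a pairing by number. The replicate block gave 3, 15 and 11 class share calls and, in mature αβ T cell-like cells, 220, 92 and 3 genes. HTODemux at its defaults, added later, called 1422 singlets for 18 h sample 2 against 7254, and the automatic Scrublet threshold in pool A called 0 doublets against 264. A sample left alone in its condition was assumed to vary like the others. Depth limits classes with under 20 cells in a sample, which had no gene test against untreated samples.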

Other observations

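The tests in this part were chosen after the class shares had been seen. Over all conditions, Il5, Il13, Il25, Il33 and Ccl11 had most of their UMIs in small classes, given here as sums of UMIs over both samples of a condition, without a test. ILC2-like cells, innate lymphocytes of type 2 immunity, held 26 of 31 UMIs of Il5, an eosinophil growth factor, and 14 of 19 UMIs of Il13 in untreated samples, 10 of 29 at 18 h, all in 1 cell, and 199 of 257 at 4 d. Basophil or mast cell-like cells held 7 of the 29 at 18 h. The 26 UMIs of Il5 came from the 124 cells of 4 d, and 0 in the 7 untreated and 23 18 h cells allow up to 96.3 and 38.6 CPM, above the 36.3 of 4 d. Il13 was seen in 4 of 7 untreated (57.1%), 1 of 23 18 h (4.35%) and 29 of 124 4 d (23.4%) ILC2-like cells. Over all conditions it was seen in 22.1% of ILC2-like and 0.054% of thymocyte-like cells, with median depths of 4674.5 and 5641 UMIs per cell. Fibroblasts and epithelial cells are not haematopoietic and lie outside the sort's gate. Thymic epithelial-like cells held 44 of 45 UMIs of Il25, the alarmin made by tuft cells, and 127 of 131 of Trpm5, a tuft cell ion channel, with 0 cells of this class in untreated samples. Fibroblast-like cells held 228 of 324 UMIs of Il33, an alarmin that acts on ILC2s, and 1151 of 1198 of Ccl11, which attracts eosinophils. Il33 was seen in 58.2% of fibroblast-like and 0.0473% of thymocyte-like cells, at median depths of 8277.5 and 5641 UMIs. Of Areg, which encodes amphiregulin, thymocyte-like cells held 69.1% of UMIs in untreated samples, 82.6% at 18 h and 44.7% at 4 d, and ILC2-like cells 26.9%, 0.298% and 30.7%. At 4 d it stood at 1214.6 CPM in ILC2-like and 76.8 in thymocyte-like cells.

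Dendritic and neutrophil-like cells were compared between 4 d and 18 h with edgeR on 2 residual degrees of freedom, since untreated samples held too few. In activated (Ccr7+) DC-like cells 362 of 7798 genes passed, 148 upward and 214 downward, in cDC1-like cells 811 of 8910, and in neutrophil-like cells 105 of 6895. In activated (Ccr7+) DC-like cells Apol7c rose by a log2 fold of 4.61 and Sult1a1 fell by 5.87. The myeloid gene Lyz2 rose by 3.79 in these cells, and C1qa, a leading gene of the macrophage-like cluster, had 2 UMIs at 18 h and 207 at 4 d (edgeR adjusted p = 0.047). Thymocyte transcripts fell there in 8 of 12 (11 down and 1 up when adjusted over the list alone), with a median of -2.27, camera adjusted p = 2e-05 and adjusted p = 0.537 with an estimated correlation. Cell cycle genes rose there in 9 of 18 (16 when adjusted over the list alone), with a median of 1.61, camera adjusted p = 6.7e-10 and adjusted p = 0.474 with an estimated correlation. In cDC1-like cells Serpine2 fell by 5.38, and interferon-stimulated genes fell in 13 of 15 (14 when adjusted over the list alone), with a median of -1.61, camera adjusted p = 1.7e-09 and adjusted p = 0.687 with an estimated correlation. In neutrophil-like cells Itgax, which encodes CD11c of dendritic cells, rose by 3.32, Adamdec1, a leading gene of the eosinophil-like cluster, by 2.90, Lyz2, the lysozyme gene, by 2.88 and Gpr183 by 2.84, and Saa3 (-5.67), an acute phase gene, and Nos2 (-5.04), the inducible nitric oxide synthase gene, fell. Thymocyte transcripts had 0 of 12 called there (9 downward when adjusted over the list alone), with a median of -1.28, camera adjusted p = 5.6e-06 and adjusted p = 0.385 with an estimated correlation. Interferon-stimulated genes fell in 6 of 14 (13 when adjusted over the list alone), with a median of -1.98, camera adjusted p = 3.2e-12 and adjusted p = 0.385 with an estimated correlation.

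An unnamed cluster of 417 cells, led by Ifitm1, Serpina3f and Cxcl10, held 110 and 296 cells at 18 h, and 2 and 5 in the untreated samples. Another of 31 cells, led by Upk3b and Msln, came from 4 d sample 2 alone.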
